A study of Arabidopsis thaliana with 9 samples.

How the data were processed

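RNA was measured by poly(A) RNA sequencing in 9 samples of young rosette leaves, 3 per genotype, each a pool of leaves from 3 plants; per the labels, RNA was extracted with a Qiagen RNeasy kit and Illumina libraries were made. The labels call the samples biological replicates. Genotype and replicate number came from the labels of each sample, and each column of the table was matched to its sample by name.

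The authors deposited 1 table with a log2 value for each of 33602 loci in each sample. Per the submitters' processing notes, FastQC, HISAT2, StringTie and the genome build TAIR10 were used; versions, settings and the annotation are not given in the sources used here. The deposited log2 values have the form log2 of a scaled abundance plus 1. This was worked out from the values themselves: with the offset of 1 removed, the lowest values of each sample are whole multiples of 1 unit in the sixth decimal after division by 1 factor per sample. These factors were 1.0777 to 1.095 in the wild type, 0.9699 to 1.0219 in 2cpab and 1.0068 to 1.0504 in ntrc-2cpab, and the 75th percentile was 2.7483 in every sample. How the authors scaled the samples is not given in the sources used here, and neither is whether the abundance was FPKM or TPM. Between 92.8 and 94.2% of the values tested came out whole within a tolerance of 0.1. The values do not step by whole reads (at most 1.95% of ratios between low loci fell in 1 bin of 0.02 log2), so the depth of each sample is unknown and no counting interval can be given. Precision is judged from the spread between replicates alone. Summed abundance ran from 960937 to 1029627 per sample, loci at 0 from 9408 to 10453, and the 10 highest loci took 37.3 to 40.4% of the sum. Scaling sets each value relative to the rest of its sample, so a change in total RNA cannot be seen.

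The reference gene table used here is of TAIR10.1, which is not named as the authors' annotation. It served for gene names (32835 of 33602 loci matched), for finding from its positions which genes overlap, and for annotation terms. Levels of genes with near-identical copies, of overlapping genes and of antisense genes are uncertain. Strand use and the treatment of shared reads are not given in the sources used here. The level of plastid- and mitochondria-encoded loci in poly(A) RNA also follows the RNA selection. Some plastid-encoded loci, such as ATCG00950 and ATCG01180, had near-identical values in every sample, so these loci do not all count independently.

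Before the data were examined, the comparisons, the tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed. Genes with a mean abundance of at least 1 over the 9 samples were tested, which left 16384. limma 3.58.1 in R 4.3.3 was run on the deposited log2 values (lmFit, contrasts.fit and eBayes with an intensity trend) with all 9 samples in 1 fit and 6 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes at low abundance. Levels are given as mean ± SD of the abundance. The verbs rose and fell are used for genes past this threshold.

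Gene lists numbered 27: 25 with 429 members written from general knowledge, all found in the table, and the plastid-encoded (133) and mitochondria-encoded (146) loci. The lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of each comparison. The estimate was above the preset in every list but leaf senescence. It reached 0.824 for photosystem cores and electron transport and 0.859 for iron deficiency. Where members vary together more than the preset assumes, the p-values at the preset are too small. For each list the genes past the threshold were also counted after adjustment over the list alone. The named genes are the mutated genes and, per comparison, up to 8 with the largest rise and up to 8 with the largest fall, together with up to 4 members of each list that passed or held at least 3 called genes. The rises and falls had to be called, to differ at least 2-fold, to have a mean of at least 5 in the higher group and to have no overlap between replicates. That gave 4 rises and 5 falls in 2cpab, 13 and 17 to choose from in ntrc-2cpab, and 0 and 1 between the mutants.

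On simulated data with 200 changed genes per comparison, the test recovered 95, 95 and 94% of genes changed by 1 on the log2 scale for 2cpab against wild type, ntrc-2cpab against wild type and ntrc-2cpab against 2cpab. It recovered 98, 98 and 97% of those changed by 2, with 10, 8 and 13 false calls among 16384 genes. The simulated noise was normal and independent between genes, with no sample that deviated as a whole. These rates need not hold for the real data, in which wild type replicate 1 stood apart. Overlap between the mutants was set beside 100 draws of unchanged groups that shared a simulated wild type. All 9 samples of a draw were made from the gene means and the deviations of samples from their group means. These deviations were drawn with replacement and given random signs, so 1 profile could enter several simulated samples.

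Alternatives were another pseudocount, other abundance filters, quantile and median-ratio scaling, fits of the genotypes compared alone, no trend, the replicate number as a block, leaving out each sample, a fold threshold and the estimated correlation. Undoing the authors' scaling, weighting samples, the simulated share of genes with the same sign in both mutants, the overlap without the mutated genes, the tests of annotation terms and the lists of mitochondrial chaperones and abscisic acid receptors were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures. No column of the table was left out.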

Results

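Poly(A) RNA was sequenced from young rosette leaves of 8-week-old Arabidopsis thaliana plants of the Col-0 accession, grown in short days and sampled after 2 h of light at 125 µE m-2 s-1. The 9 samples fell into 3 genotypes with 3 biological replicates each, and each replicate was a pool of leaves from 3 plants. The genotypes were the wild type, the mutant 2cpab, which lacks the chloroplast 2-Cys peroxiredoxins A and B, and the mutant ntrc-2cpab, which also lacks NTRC, the chloroplast NADPH-dependent thioredoxin reductase C. 2-Cys peroxiredoxins reduce hydrogen peroxide in the chloroplast, and NTRC reduces them. The deposited table gave 1 log2 value per sample for 33602 loci, and the abundances given here were calculated back from it. The number of reads per sample is unknown, because the table holds scaled abundances and no counts. Between 16166 and 16403 loci per sample had an abundance of at least 1, and loci of the plastid genome took 46.8 to 55.9% of the summed abundance.

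The mutated genes were examined first. 2CPA (AT3G11630) had an abundance of 298 ± 34.7 (SD, n = 3) in the wild type, 4.34 ± 0.575 in 2cpab and 3.77 ± 0.309 in ntrc-2cpab, so that 2cpab kept 1.46% of the wild-type level. 2CPB (AT5G06290) stood at 58.6 ± 5.26 in the wild type, 9.77 ± 0.742 in 2cpab and 9.65 ± 1.04 in ntrc-2cpab. NTRC (AT2G41680) stood at 76.9 ± 2.93 in the wild type and 64.6 ± 3.62 in 2cpab, a difference that did not pass the test (log2 fold change -0.25, limma with Benjamini-Hochberg adjusted p = 0.217). In ntrc-2cpab NTRC stood at 16 ± 2.01, which was 20.8% of the wild-type level. In single samples NTRC ranged from 14.7 to 18.3 in ntrc-2cpab and from 60.9 to 80.2 in the other 6 samples, and 2CPA from 259 to 325 in the wild type and from 3.43 to 4.85 in the mutants. Each sample carried the loss that its label names.

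**Figure D1:**
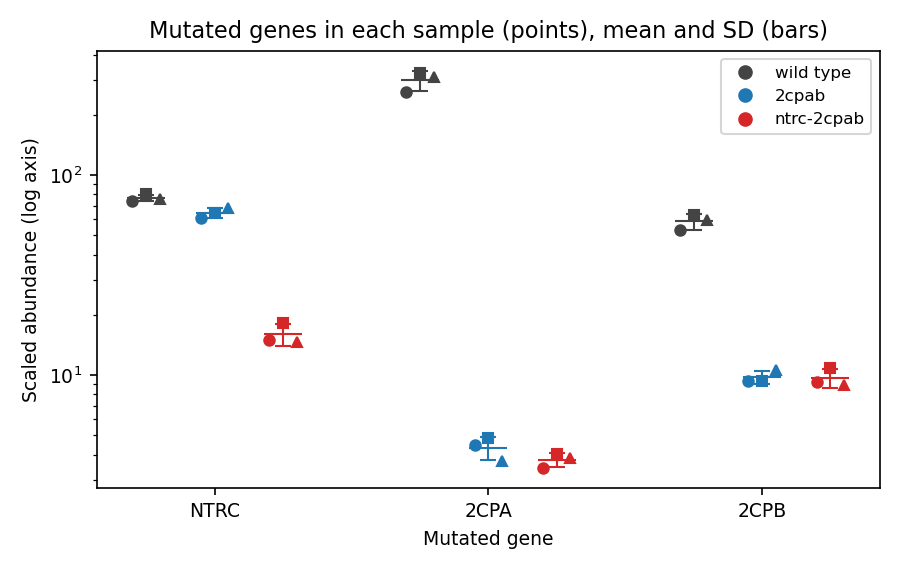
Abundance of NTRC, 2CPA and 2CPB on a log axis in each of the 9 samples (points) with the mean and SD of each genotype (n = 3). 2CPA lies between 259 and 325 in the wild type and below 5 in every mutant sample, and NTRC is low in the 3 ntrc-2cpab samples alone.

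The wild-type samples differed more from each other than the mutant samples did. The first principal component, with 37% of the variance, placed wild type replicates 1, 3 and 2 at -36.2, -18.3 and -4.42, the 2cpab samples between 1.28 and 7.57 and the ntrc-2cpab samples between 9.3 and 20.8. The SD between replicates, as a root mean square over genes on the log2 scale, was 0.23 in the wild type, 0.18 in 2cpab and 0.20 in ntrc-2cpab. Immune genes differed between replicates. PR1, a pathogenesis-related gene, had an abundance of 0.259, 24.4 and 3.9 in wild type replicates 1, 2 and 3, 12.4, 8.67 and 26.5 in 2cpab and 1.61, 40.6 and 49.6 in ntrc-2cpab. The median deviation of 16 genes of the salicylic acid and immune list from their 9-sample means was -0.87, 0.47 and -0.37 in the wild type, 0.23, 0.034 and 0.092 in 2cpab and -0.019, 0.026 and 0.38 in ntrc-2cpab. Wild type replicate 1 was also highest at the ribosomal RNA locus AT2G01020. This locus stood at 338 in that sample and between 72.9 and 161 in the other 8 samples.

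**Figure D2:**
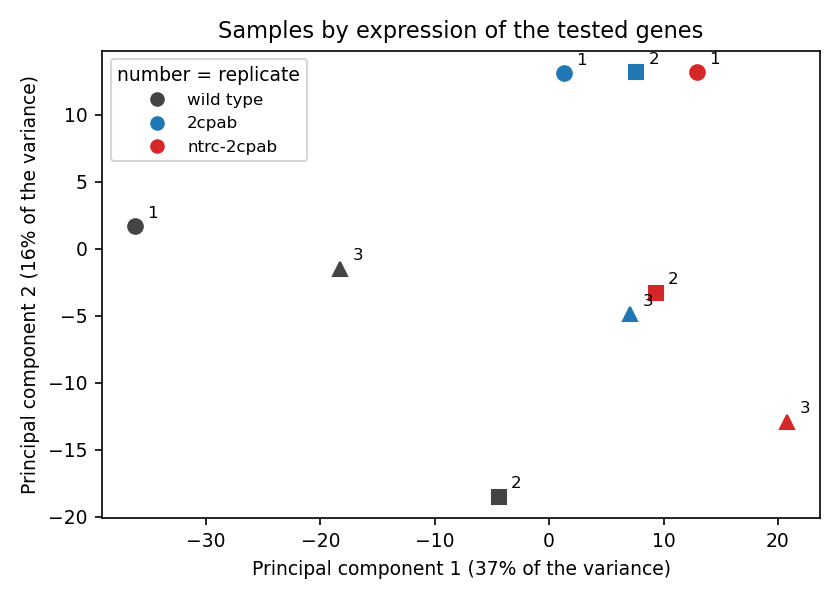
Scores of the 9 samples on the first (37% of the variance) and second (16%) principal components of the log2 values of the 16384 tested genes. Wild type replicate 1 lies farthest from the mutants at -36.2 and wild type replicate 2 nearest to them at -4.42.

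The comparison of 2cpab with the wild type asks what the loss of both 2-Cys peroxiredoxins does to the leaf transcriptome. The labels name no independent lines, so other differences between a mutant and the wild type cannot be told apart from the mutations. Of the 9 measured members of the heat shock list 3 rose, among 22 genes that passed the test. HSP70-4 (AT3G12580), a cytosolic HSP70 chaperone, stood at 66.8 ± 22.9 in 2cpab and 6.79 ± 1.83 in the wild type (n = 3 each, log2 fold change 3.08 ± 0.334 SE, limma with Benjamini-Hochberg adjusted p = 0.0139). HSP90.1 (AT5G52640), a heat-induced cytosolic HSP90, stood at 8.93 ± 2.39 against 2.16 ± 0.524 (log2 fold change 1.64, limma adjusted p = 0.0139). HSP23.5 (AT5G51440), a mitochondrial small heat shock protein, rose by 1.77 on the log2 scale. Across 16384 tested genes, 11 were higher and 11 were lower in 2cpab (limma, 6 residual degrees of freedom), of which 5 and 6 differed at least 2-fold.

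Of the 9 measured members of the heat shock list, 3 rose and 6 did not pass the test over all genes, and 7 were higher when adjusted over the list alone. The list median was 1.05 on the log2 scale, and the list passed the set test (camera adjusted p = 1.99e-07, and adjusted p = 0.327 with an estimated correlation). Members that did not pass over all genes included HSP17.6II at 1.99 and HSP101 at 0.86, while the plastid chaperone CLPB3 stood at -0.15. AT5G48570, an FKBP-type peptidyl-prolyl isomerase, rose by 1.44. Among the other genes that rose were 3 for mitochondrial chaperones: CPN10 (0.77), MTHSC70-2 (0.66) and Hsp89.1 (0.60). The remaining rises were AT3G13525, a small nucleolar RNA, at 1.07, EMB2729 at 0.76, AT5G22100 at 0.66 and ABH1 at 0.50. These genes were named after their values were seen, except HSP70-4, HSP90.1, HSP23.5, HSP17.6II, AT5G48570 and AT3G13525, which the naming rule gave.

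Apart from 2CPA and 2CPB, the largest fall was that of MRD1 (AT1G53480). It stood at 9.41 ± 0.422 in the wild type and 0.0683 ± 0.0745 in 2cpab (log2 fold change -3.29, limma adjusted p = 0.00326). ARP9 (AT5G43500), an actin-related protein gene, stood at 7.75 ± 0.07 in the wild type and 3.17 ± 0.163 in 2cpab (log2 fold change -1.07, limma adjusted p = 0.00026). AT3G28270 fell to 1.17 ± 0.345 from 5.27 ± 1.91. On the log2 scale the pseudogene AT5G35935 fell by 1.21, the noncoding locus AT4G13495 by 0.78, AGL42 by 0.72, AT4G13575 by 0.68, the aquaporin gene PIP2B by 0.60 and CYP38, a thylakoid lumen cyclophilin, by 0.47. PIP2B has near-identical copies, and its value is uncertain to that extent.

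Genes of photosynthesis were slightly lower as groups, and none of their nuclear members passed the test over all genes. All 18 members of the light-harvesting antenna list were lower, with a median of -0.25 (camera adjusted p = 1.15e-07). Of 30 genes for photosystem cores and electron transport 29 were lower, with a median of -0.23 (camera adjusted p = 6.94e-09), and of 21 genes of the Calvin-Benson cycle 20 were lower, with a median of -0.26 (camera adjusted p = 5.09e-08). For each of these lists the adjusted p was 0.497 with an estimated correlation. Adjusted over the list alone, 8, 9 and 7 members were lower. PSBO1, of the oxygen-evolving complex, stood at 1738 ± 97.9 in 2cpab and 2128 ± 124 in the wild type, RBCS2B, a Rubisco small subunit gene with near-identical copies, at 1231 ± 238 and 2046 ± 332, and CP12-2, a regulator of the cycle, at 149 ± 12.6 and 203 ± 11.7. The median deviation of the photosystem list was -0.08, 0.25 and 0.15 in wild type replicates 1, 2 and 3, and wild type replicate 1 thus lay within the range of the mutants.

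Chlorophyll and tetrapyrrole synthesis (29 genes, median -0.17, camera adjusted p = 8.32e-06) and starch metabolism (31 genes, median -0.13, camera adjusted p = 0.000276) also passed as lower lists, with adjusted p = 0.497 and 0.544 with an estimated correlation. The starch median ran from -0.23 to -0.069 over the 9 fits that left out 1 sample. Examples were CAO, at 72.3 ± 4.08 against 93.7 ± 3.27, and BAM1, a plastid beta-amylase, at 14.2 ± 0.473 against 19.2 ± 1.76. The 12 sugar starvation markers had a median of -0.19, the 20 genes of the plastid thioredoxin system -0.10, the 13 of cold and abscisic acid response -0.16, the 14 of the circadian clock -0.23 and the 7 guard cell markers -0.25. These passed the set test at camera adjusted p between 0.0142 and 0.0233, and none passed with an estimated correlation, where adjusted p lay between 0.497 and 0.544. Of the 9 fits that left out 1 sample, the sugar starvation call held in 9, circadian clock in 8, cold and abscisic acid in 7, and the thioredoxin system and guard cell markers in 6 each. Single genes of these lists, none of which passed over all genes, included the f-type thioredoxin TRXF2 (log2 fold change -0.44), ASN1 (-0.98), COR15A (-0.54), LNK1 (-0.27) and the potassium channel KAT1 (-0.53).

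Aliphatic glucosinolate synthesis was lower in all 16 measured genes, with a median of -0.54 (camera adjusted p = 2.69e-06, and adjusted p = 0.497 with an estimated correlation). CYP79F1, which starts the core pathway, stood at 19.4 ± 2.15 in 2cpab and 37.9 ± 12.4 in the wild type. Flavonoid and anthocyanin synthesis (12 genes, median -0.26, camera adjusted p = 0.00489, and adjusted p = 0.497 with an estimated correlation) included the regulator PAP1 at 4.07 ± 1.91 against 9.29 ± 4.91. The iron deficiency list (11 genes, median -0.59, camera adjusted p = 0.0212, and adjusted p = 0.639 with an estimated correlation) included IMA3 at 72.1 ± 9.71 against 150 ± 94.1. Its call ended without wild type replicate 1, wild type replicate 3 or 2cpab replicate 3, at medians of -0.28, -0.20 and -0.31. No member of these 3 lists passed over all genes or adjusted over the list alone. Their wild-type replicates disagreed: median deviations in replicates 1, 2 and 3 were 0.87, -0.02 and 0.64 for glucosinolate genes and 0.93, -0.87 and 1.45 for iron genes. The immune list was higher in 15 of 16 genes, with a median of 0.47 (camera adjusted p = 0.00449, and adjusted p = 0.544 with an estimated correlation). Without wild type replicate 1 its median was 0.23 and it no longer passed (camera adjusted p = 0.209). PR5 stood at 64.6 ± 15.7 in 2cpab and 33 ± 31.2 in the wild type, where single samples held 10.7, 68.7 and 19.7.

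The 133 plastid-encoded loci had a median of -0.025 (camera adjusted p = 0.0211, and adjusted p = 0.655 with an estimated correlation), which turned to 0.028 with quantile normalization and to 0.035 without wild type replicate 1. None passed over all genes, and 15 were lower when adjusted over the list alone. Among them was psaB (ATCG00340), at 8439 ± 931 against 12340 ± 978. The level of plastid-encoded loci in poly(A) RNA also follows the RNA selection. Of the 27 lists 16 passed, 2 as higher and 14 as lower, and 0 passed with an estimated correlation. At a mean abundance of at least 5 the calls of the sugar starvation, cold and abscisic acid, flavonoid, iron deficiency and guard cell lists ended. With array weights those of the sugar starvation, cold and abscisic acid, circadian clock and plastid-encoded lists ended. With no filter on low abundance and with the authors' scaling undone 14 of the 16 lists stayed in each case, and with quantile normalization 15. When 1 sample was left out, 9 of the 16 medians moved by over 1.5 times or changed sign, and 9 lists kept their call in all such fits. The lists that did not pass were plastid antioxidant enzymes, oxidative stress, jasmonate, leaf senescence, sulfate assimilation and glutathione, cell proliferation, phloem, xylem, trichome and flowering markers and mitochondria-encoded loci, at camera adjusted p from 0.0705 to 0.969. In 3 of these 11 lists (oxidative stress, leaf senescence and xylem) the median and the test had opposite signs.

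The count of 22 genes rested on single samples. It was 6, 116 and 12 without wild type replicates 1, 2 and 3, 8 and 4 without 2cpab replicates 1 and 2, and 9 without ntrc-2cpab replicate 2. With the authors' scaling between samples undone, 327 genes were higher and 23 lower, and with quantile normalization 17 and 11. With no filter on low abundance the calls of HSP70-4, HSP90.1 and HSP23.5 ended (limma adjusted p = 0.0507, 0.0507 and 0.0836), and of 10 named genes called only 2CPA, 2CPB, MRD1 and ARP9 stayed. The call of HSP70-4 also ended without wild type replicate 3, 2cpab replicate 1 or 2cpab replicate 2 (limma adjusted p = 0.054, 0.0581 and 0.103), at log2 fold changes from 2.88 to 2.98, and MRD1 and ARP9 kept theirs in all 9 such fits. HSP90.1 kept its call in 7 of them, AT3G13525 in 5, HSP23.5 in 4, AT5G48570 in 2 and AT3G28270 in 1. The plastid-encoded call held in 6.

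The comparison of ntrc-2cpab with the wild type asks what the loss of NTRC together with both peroxiredoxins does. In ntrc-2cpab 427 genes were higher and 218 were lower (limma with Benjamini-Hochberg adjustment, 16384 genes), of which 21 and 23 differed at least 2-fold. The largest rise was again that of HSP70-4. It stood at 44.2 ± 16.6 in ntrc-2cpab and 6.79 ± 1.83 in the wild type (n = 3 each, log2 fold change 2.49, limma adjusted p = 0.0129). AT4G21870, an HSP20-like gene, stood at 24.4 ± 11.6 against 3.94 ± 2.75, AT1G72416, a DnaJ-domain gene, at 18.9 ± 7.24 against 5.08 ± 2.25, and HSP90.1 at 6.6 ± 0.117 against 2.16 ± 0.524. GSTF6, a glutathione transferase gene with a near-identical neighbour, GSTF7, rose to 39.3 ± 14.5 from 11.5 ± 6.45. AT4G34950, a major facilitator transporter, rose by 1.19, XYL4, a beta-xylosidase, by 1.15, and AT5G48570 by 1.14.

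In the heat shock list 4 of 9 measured genes rose, over all genes and adjusted over the list alone: HSP70-4, HSP17.6II (log2 fold change 1.81), HSP23.5 (1.45) and HSP90.1 (1.28). The list median was 0.46 (camera adjusted p = 0.000709, and adjusted p = 0.652 with an estimated correlation). Of the immune list none of 16 genes passed, at a median of 0.54 (camera adjusted p = 0.0226, and adjusted p = 0.742 with an estimated correlation). The call of that list ended without wild type replicate 1, wild type replicate 3 or ntrc-2cpab replicate 3, with medians of 0.19, 0.40 and 0.27. PR5 stood at 71.4 ± 20.2 against 33 ± 31.2.

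After 2CPA the largest falls were MRD1, at 0.54 ± 0.848 against 9.41 ± 0.422 (log2 fold change -2.89, limma adjusted p = 0.00448), and AT4G04223, at 0.797 ± 0.557 against 10.4 ± 1.71 (log2 fold change -2.69, limma adjusted p = 0.00432). AT2G16367 and AT1G33370 fell by 2.17 and 2.02. EXPB3, a beta-expansin of the cell wall, stood at 6.19 ± 1.55 against 16 ± 3.61.

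In aliphatic glucosinolate synthesis all 16 genes were lower, with a median of -0.91 (camera adjusted p = 5.63e-08, and adjusted p = 0.68 with an estimated correlation). None passed over all genes and 15 were lower when adjusted over the list alone. CYP79F1 stood at 15.5 ± 7.92 against 37.9 ± 12.4, and LEUD1, of side-chain elongation, at 5.77 ± 2.73 against 15.5 ± 6.04. In single samples the median deviation was -0.67, 0.05 and -0.58 in ntrc-2cpab replicates 1, 2 and 3, against 0.87, -0.02 and 0.64 in the wild type, so replicate 2 of each genotype lay close to the other. In flavonoid and anthocyanin synthesis 2 of 12 genes fell, 6 were lower adjusted over the list alone, and the median was -0.60 (camera adjusted p = 0.00016, and adjusted p = 0.68 with an estimated correlation). CHI (AT3G55120), chalcone isomerase, stood at 4.74 ± 1.01 against 7.1 ± 0.0846, and UGT75C1, an anthocyanin glucosyltransferase, at 1.36 ± 0.237 against 3.28 ± 0.678. Of the 9 fits that left out 1 sample, the call of CHI held in 0 and that of UGT75C1 in 5.

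In sulfate assimilation and glutathione 2 of 7 genes fell, over all genes and over the list alone: APR1, an adenylylsulfate reductase gene, to 12.3 ± 1.07 from 23.2 ± 4.35, and GGCT2;1, which recycles glutathione, to 2.34 ± 0.712 from 4.35 ± 0.555. The list median was -0.16 (camera adjusted p = 0.0154, and adjusted p = 0.652 with an estimated correlation). All 11 iron deficiency genes were lower, with a median of -0.90, and none passed alone (camera adjusted p = 0.000709, and adjusted p = 0.742 with an estimated correlation). The wild-type values of this list ran from -0.87 to 1.45, and its median from -1.70 to -0.70 when 1 sample was left out. The circadian clock list had a median of -0.29 with 7 of 14 genes lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.68 with an estimated correlation). It included LNK2 at -0.58 and RVE8 at -0.59, neither of which passed over all genes. The call of that list ended without wild type replicate 2 (camera adjusted p = 0.0922). Of the 9 fits that left out 1 sample, GGCT2;1 was called in 3 and APR1 in 6.

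Photosynthesis lists were lower here too. In the Calvin-Benson cycle 2 of 21 genes fell: CP12-2, to 152 ± 0.258 from 203 ± 11.7, and RBCS2B, to 1285 ± 32.1 from 2046 ± 332. The list median was -0.21 (camera adjusted p = 2.56e-05, and adjusted p = 0.68 with an estimated correlation). The antenna list had a median of -0.13, photosystem cores and electron transport -0.11 and chlorophyll synthesis -0.11 (camera adjusted p = 0.00956 each, and adjusted p = 0.742 with an estimated correlation). In the last of these CAO fell by 0.32, and no member of the antenna or photosystem list passed over all genes. Adjusted over the list alone, 0 genes of chlorophyll synthesis passed. The call of CAO held in 0 of the 9 fits that left out 1 sample (limma adjusted p from 0.0647 to 0.138), RBCS2B in 1 and CP12-2 in 3. Without wild type replicate 2 the calls of the antenna, photosystem and chlorophyll lists ended, at medians of -0.09, -0.028 and -0.053. Without wild type replicate 3 those of the antenna and photosystem lists ended. In starch metabolism (median -0.09, camera adjusted p = 0.0231, and adjusted p = 0.742 with an estimated correlation) MEX1, the maltose exporter, fell by 0.33 with a call that held in 1 of these 9 fits, and the call of the list ended without wild type replicate 2 or ntrc-2cpab replicate 1.

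Of the 27 lists 12 passed, 2 as higher and 10 as lower, and 0 with an estimated correlation. At a mean abundance of at least 5 the calls of the heat shock, immune and sulfate lists ended. With array weights those of the starch and circadian clock lists ended. With no filter on low abundance, with the replicate block and with the authors' scaling undone, 11 of the 12 lists stayed in each case. When 1 sample was left out, 8 of the 12 medians moved by over 1.5 times or changed sign, and 6 lists kept their call in all such fits. Lists that did not pass, at camera adjusted p from 0.0561 to 0.888, still held single genes that did. TRXF2 fell by 0.39 in the plastid thioredoxin system, and GR2, a glutathione reductase, by 0.41 and VTE1, tocopherol cyclase, by 0.52 among plastid antioxidant enzymes. MCCA fell by 0.31 and ABI2 by 0.47. SWEET11, a phloem sucrose transporter, rose to 18.8 ± 4.24 from 9.59 ± 1.23. Of the plastid-encoded loci psaB fell by 0.46, psaA (ATCG00350) fell by 0.45 and ATCG00260 rose by 0.63. Of the mitochondria-encoded loci ATMG00820 rose by 0.35. The level of both kinds of loci in poly(A) RNA also follows the RNA selection. The calls of psaA (ATCG00350) and psaB (ATCG00340) ended with quantile normalization, and of the 9 fits that left out 1 sample they held in 2 and 1. The members of these lists were named after their values were seen, except ATCG00260, psaA and psaB. For the members named so, it was not examined whether the call held with 1 sample left out. In 3 lists that did not pass (plastid thioredoxin system, leaf senescence and phloem) the median, the mean and the test differed in sign.

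The count of 645 genes also rested on single samples. It was 49 and 392 without wild type replicates 1 and 3, 295 and 298 without 2cpab replicates 2 and 3, and 56, 200 and 174 without ntrc-2cpab replicates 1, 2 and 3. In all 645 genes the replicates of the genotypes compared did not overlap, so leaving out 1 sample could not change a direction. Chosen with the same samples, all 645 kept an unadjusted limma p under 0.05 without wild type replicate 1, where 47 of them passed. Of 29 named genes 6 were still called there: the mutated genes, HSP70-4, MRD1 and AT4G04223. Among the largest rises AT4G21870, GSTF6, AT1G72416, AT4G34950 and XYL4 lost the call (limma adjusted p from 0.102 to 0.118). Of all 9 fits that left out 1 sample, XYL4 was called in 2 and the other 4 genes in 3 each. With the authors' scaling undone 823 genes were higher and 142 lower.

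**Figure D3:**
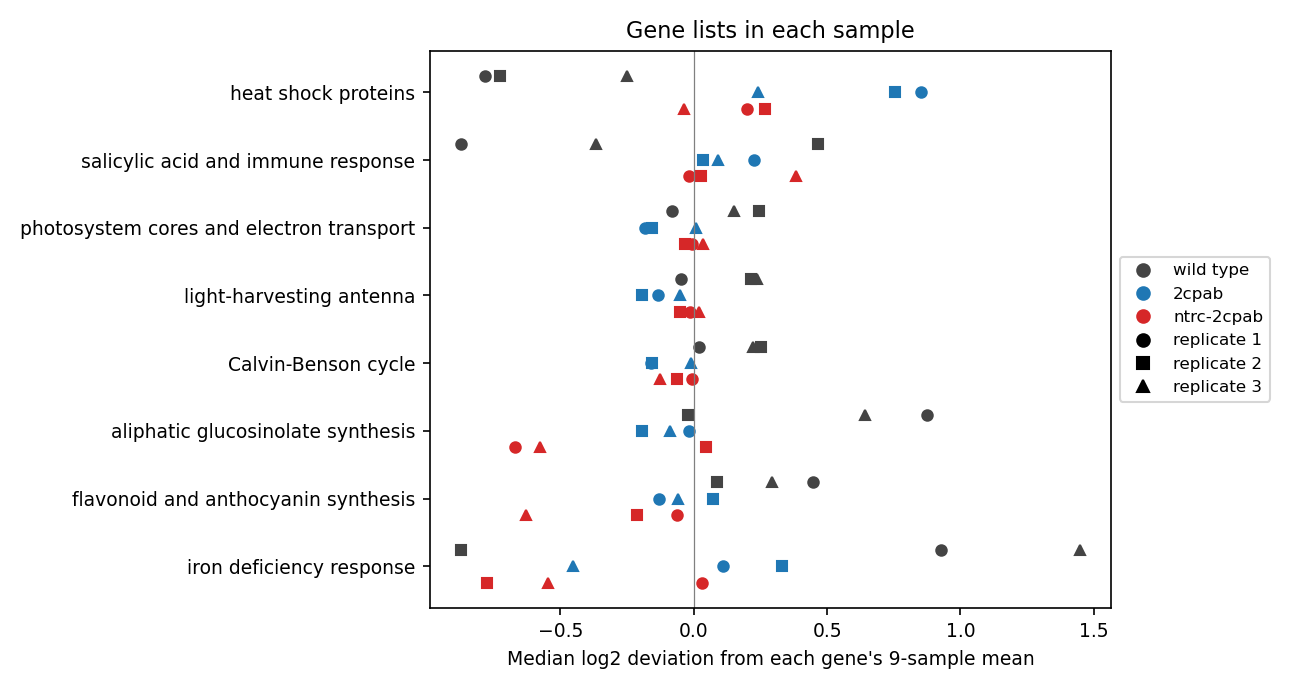
Median over each list of the log2 value minus each gene's mean over the 9 samples, for 8 gene lists in each sample (colour, genotype; shape, replicate). Heat shock genes lie below 0 in the 3 wild-type samples and above 0 in the 3 2cpab samples, and the immune, glucosinolate and iron lists spread widely among the wild-type samples.

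The overlap of the comparisons asks whether the mutants share their changes. Of the 22 genes called in 2cpab, 20 were called in the same direction in ntrc-2cpab, 11 as higher and 9 as lower. The 9 lower genes include 2CPA and 2CPB, which are mutated in both genotypes. Without the mutated genes 11 higher and 7 lower genes were shared, where independent lists of the same lengths would share 0.287 and 0.118. The exceptions were AT4G13495 and AT5G35935, at -0.32 and -0.18 in ntrc-2cpab. Because both comparisons use the same wild-type samples, unchanged groups that shared a simulated wild type were drawn 100 times. All 9 samples of a draw came from deviations resampled with replacement. The same profile could thus recur in several of them, which may widen the range of the draws. These draws shared a mean of 0.91 higher and 0.85 lower genes, with at most 47 and 50. The shared counts of 95% of draws lay between 0 and 1.05 for higher and between 0 and 0.525 for lower genes. The log2 fold changes correlated across genes with r = 0.822 (genes are not independent replicates), against a simulated mean of 0.494 with 95% of draws between -0.295 and 0.942, so unchanged groups can give such a correlation. Their covariance was 0.0545 against 0.0151, with 95% of draws between -0.004 and 0.0444 and a highest draw of 0.0629. With 3 wild-type samples the controls cannot be split, and part of the excess may come from them. Other differences that both mutant lines share cannot be told apart from the shared mutations either. Of 642 genes called in ntrc-2cpab besides the mutated genes, 638 (99.4%) had the same sign in 2cpab, where the median change was 0.734 of that in ntrc-2cpab. The 642 genes with the smallest p in each draw of unchanged groups gave a mean of 84.1% and a ratio of 0.555, with 95% of draws from 11.3 to 100% and from -0.342 to 1.59. The shared sign and size therefore do not by themselves show a shared response. The shared count of 20 was 4 without 2cpab replicate 2 and 108 without wild type replicate 2.

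**Figure D4:**
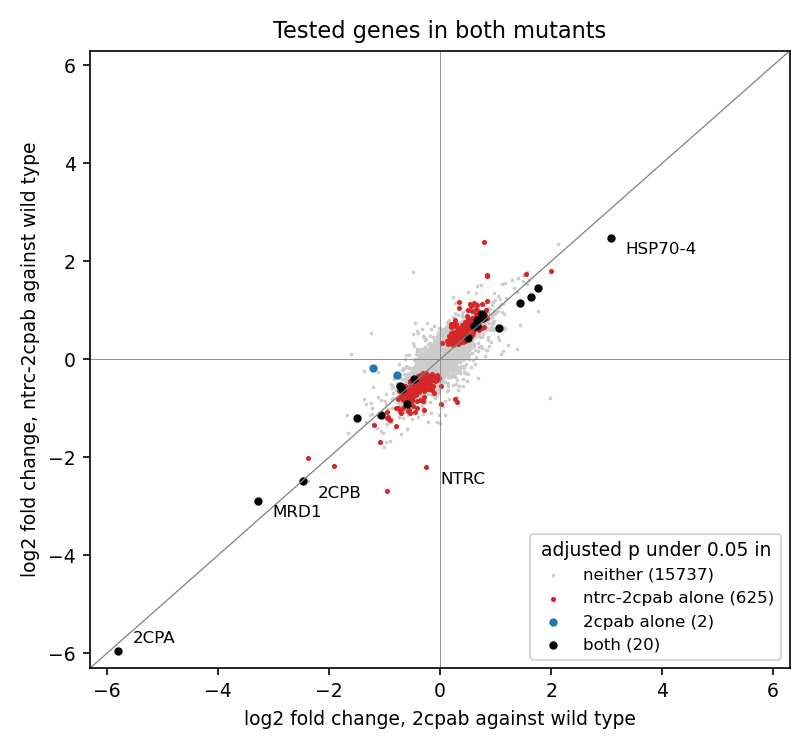
Log2 fold change of each tested gene in 2cpab (x axis) and ntrc-2cpab (y axis), both against the same 3 wild-type samples, with the genes called in each comparison coloured. The values correlate with r = 0.822, part of which comes from the shared wild-type samples (simulated mean 0.494, with 95% of draws between -0.295 and 0.942).

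The comparison of ntrc-2cpab with 2cpab asks what the further loss of NTRC adds when the 2-Cys peroxiredoxins are already missing. NTRC was the only gene that passed: it stood at 16 ± 2.01 in ntrc-2cpab and 64.6 ± 3.62 in 2cpab (log2 fold change -1.95, limma with Benjamini-Hochberg adjusted p = 5.39e-05). No gene was higher and 1 was lower, and the next smallest adjusted p by limma was 0.167. At an unadjusted p under 0.05 limma gave 708 genes, where chance alone would give 819. The chaperones that rose in both mutants did not differ between them by the test, with HSP70-4 at 44.2 ± 16.6 in ntrc-2cpab and 66.8 ± 22.9 in 2cpab, and HSP90.1 at 6.6 ± 0.117 and 8.93 ± 2.39. A difference that misses the threshold does not show equal levels.

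At the preset correlation 12 of 27 gene lists passed the set test between the mutants, with small shifts, and 0 passed with an estimated correlation. Higher in ntrc-2cpab were plastid-encoded loci (109 of 133 loci, median 0.08, camera adjusted p = 1.05e-05), photosystem cores and electron transport (29 of 30 genes, median 0.11, camera adjusted p = 1.41e-05) and the antenna (18 of 18 genes, median 0.12, camera adjusted p = 0.000893). Also higher were jasmonate response (17 of 18 genes, median 0.35, camera adjusted p = 0.0063), the plastid thioredoxin system (16 of 20 genes, median 0.07, camera adjusted p = 0.0293) and flowering markers (2 of 2 genes, median 0.24, camera adjusted p = 0.0433). Lower were glucosinolate synthesis (15 of 16 genes, median -0.25, camera adjusted p = 0.000936), xylem markers (5 of 5 genes, median -0.24, camera adjusted p = 0.00123), heat shock proteins (8 of 9 genes, median -0.32, camera adjusted p = 0.00348) and flavonoid synthesis (10 of 12 genes, median -0.26, camera adjusted p = 0.00348). Iron deficiency (11 of 11 genes, median -0.57, camera adjusted p = 0.00562) and sulfate assimilation (6 of 7 genes, median -0.13, camera adjusted p = 0.0318) were lower as well. With an estimated correlation the adjusted p of these lists lay between 0.566 and 0.681. The level of plastid-encoded loci in poly(A) RNA also follows the RNA selection. No list member passed over all genes, and adjusted over the list alone 1 did, in the flowering list. LHCA1, an antenna gene of photosystem I, stood at 2014 ± 99.9 in ntrc-2cpab and 1689 ± 165 in 2cpab, LOX2, of jasmonate synthesis, at 393 ± 142 and 298 ± 55.3, and FMOGSOX1, a glucosinolate oxygenase, at 3.37 ± 1.35 and 5.61 ± 1.52. The other 15 lists did not pass (camera adjusted p from 0.0677 to 0.885), and in 4 of them the median or mean and the test differed in sign.

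The jasmonate median turned to -0.02 without ntrc-2cpab replicate 3, and its call also ended without 2cpab replicate 1. The antenna call ended with quantile normalization and without 2cpab replicate 2, the thioredoxin system call ended with quantile normalization too, and the calls of the photosystem, plastid-encoded and xylem lists held in all 9 fits that left out 1 sample. Of these 9 fits the flowering call held in 2, the thioredoxin system in 5, sulfate assimilation in 6, iron deficiency in 7, and glucosinolate, flavonoid and heat shock in 8 each. The medians of 10 of the 12 lists moved by over 1.5 times or changed sign: flavonoid synthesis ran from -0.39 to -0.022, glucosinolate synthesis from -0.46 to -0.11 and iron deficiency from -0.82 to -0.25. The plastid-encoded call ended with quantile normalization (median -0.0004, camera adjusted p = 0.559), and the xylem, thioredoxin system, heat shock and sulfate assimilation calls ended at a mean abundance of at least 5. With array weights those of the thioredoxin system, sulfate assimilation and flowering lists ended.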

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

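Undoing the authors' scaling and weighting the samples were chosen after seeing the data; the other alternatives were planned. Counts are given as higher and lower genes in 2cpab against wild type, in ntrc-2cpab against wild type and in ntrc-2cpab against 2cpab, then genes changed in the same direction in both mutants. As reported they were 11 and 11, 427 and 218, 0 and 1, and 20. With no filter they were 1 and 6, 143 and 89, 1 and 4, and 6. A mean abundance of at least 5 gave 7 lower genes in 2cpab, and quantile normalization 17 higher. Fits of the genotypes compared alone gave 1 and 5, 35 and 15, 0 and 2, and 5. With the replicate block they were 4 and 5, 251 and 106, 0 and 1, and 8. The deviations of same-numbered samples were weakly correlated (from -0.156 to 0.21). No range for unpaired samples was calculated, so a batch shared by the replicate numbers cannot be excluded. With the authors' scaling undone they were 327 and 23, 823 and 142, and 315 in the same direction; the median log2 fold change of all genes was then 0.099 in 2cpab and 0.064 in ntrc-2cpab. With array weights, 93 and 71 genes were called in 2cpab and 130 in both mutants. A log2 change of at least 1 left 5 and 6, 21 and 23, and 9. With an estimated correlation 0, 0 and 0 lists passed, in place of 16, 12 and 12. For the other changes the cause was not tested. Pseudocount, median-ratio scaling and no trend left every count within 1.5 times the reported one.

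Leaving out each sample gave 0 to 81 higher and 4 to 35 lower genes in 2cpab, 35 to 487 and 14 to 274 in ntrc-2cpab, 0 to 1 and 1 to 2 between the mutants, and 4 to 108 in both. Lists past the threshold ran from 12 to 17, 8 to 16 and 7 to 15. The highest gene counts against wild type came without wild type replicate 2 and the lowest in ntrc-2cpab without wild type replicate 1. Over all alternatives, values of named genes stayed on their side of the threshold 3238 times, which includes genes never called. They lost the call 236 times, gained it 36 times and reversed 5 times. As reported, only 10 named genes were called in 2cpab, 29 in ntrc-2cpab and 1 between the mutants, and the losses fell on these alone. Called lists kept their call 675 times, lost it 122 times and reversed 2 times. A list counts as reversed when its set test changed direction. The plastid-encoded median in 2cpab against wild type was 0.028 with quantile normalization against -0.025 as reported. Between the mutants, 2CPB, at -0.019 as reported, was at -0.0966 without ntrc-2cpab replicate 2, 0.0376 without 2cpab replicate 3, 0.0074 without ntrc-2cpab replicate 1, 0.033 without ntrc-2cpab replicate 3 and 0.0188 with array weights. Without ntrc-2cpab replicate 3, GSH2 was at -0.00506 against 0.14 as reported, and the jasmonate median, which had passed at 0.35, was at -0.0158; without ntrc-2cpab replicate 1 they were 0.266 and 0.643. The count-based test planned for counts was not run because the table holds none, and flowering markers have no value at a mean of at least 5. Depth is unknown, so its limit cannot be stated.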

Other observations

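All the tests in this part were chosen after the calls were seen, except those of overlapping genes, of neighbouring loci and of left-out ntrc-2cpab samples, which were planned before their results were seen. Genes higher in ntrc-2cpab than in wild type were rich in nucleolar and mitochondrial functions by annotation terms (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted). Of 294 such genes with a location term, 40 were nucleolar, 7.56 times the 5.29 that chance would give (adjusted p = 2e-22), and 47 were mitochondrial (2.65-fold, adjusted p = 2.72e-08). Ribosome biogenesis (11 genes, 4.13-fold, adjusted p = 0.00265), protein folding (19 genes, 3.68-fold, adjusted p = 5.59e-05) and response to heat (10 genes, 8-fold, adjusted p = 2.97e-05) also passed. Among them the rRNA processing gene FIB2, fibrillarin, rose to 28.1 from 14.8 (log2 fold change 0.88), NUC-L1, nucleolin, to 106 from 63 (0.75) and NOP56 to 51.2 from 29.7 (0.77). Over all 185 tested nucleolar genes the median log2 fold change was 0.24 in ntrc-2cpab, with 88.1% above 0. It was 0.21 in 2cpab and 0.2 in ntrc-2cpab without wild type replicate 1. Their median deviation from the 9-sample means was -0.25, -0.17 and -0.048 in wild type replicates 1, 2 and 3. Fisher's exact test treats genes as independent, so its p-values do not measure the spread between samples. In ntrc-2cpab the whole mitochondrial term had a median of 0.075 with 66.1% above 0, and protein folding 0.093 with 62.1%; without wild type replicate 1 these medians were 0.052 and 0.054. Without that sample the nucleolar term no longer passed among the 31 annotated higher genes (2 genes, adjusted p = 1), while the mitochondrial term did (9 genes, 4.81-fold, adjusted p = 0.00569), as did cell wall (5 genes, adjusted p = 0.0411, and 22 genes, adjusted p = 0.000104 with all samples), and 0 process terms passed. No term passed among the lower genes (smallest adjusted p = 0.0604).

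Of 10 measured mitochondrial chaperone genes, 4 rose in 2cpab (median log2 fold change 0.59) and 9 in ntrc-2cpab (median 0.68), and all 10 were above 0 in both. Without wild type replicate 1, 4 of them passed in ntrc-2cpab at a median of 0.64. Between the mutants 0 passed by limma and the median was 0.07. Of 9 abscisic acid receptor genes 5 rose in ntrc-2cpab by limma: PYL6 (log2 fold change 1.73), PYL5 (1.12), PYL4 (0.99), PYR1 (0.73) and RCAR3 (0.51). None passed without wild type replicate 1, where the median moved from 0.51 to 0.48, and none passed in 2cpab, where the median was 0.25.

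The wild-type replicates differed from each other in immune genes: 15 of 16 list members were higher in replicate 2 than in replicate 1, by a median of 1.5. A mislabelled sample is argued against by 2CPA, whose lowest wild-type value was 53.4 times the highest mutant value. The authors' scaling is argued against by its factors of 1.095 and 1.0805 in replicates 1 and 2, which are too alike to give this difference. Undoing the scaling could therefore hardly move the difference, which was then 1.51. A shift of all genes alike, from organelle and ribosomal transcripts, is argued against because the median of all tested genes differed by 0.01 under these similar factors. The immune list lay at percentile 100 of 10000 random lists matched on abundance, whose highest median was 0.311. This percentile adds no support, since the list was examined because it differed. No biological explanation was tested, since no label separates the wild-type replicates.

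In 18 loci the 9 samples fell into a low and a high set with a gap of at least 2 on the log2 scale that divided replicates of a genotype. AT4G23420 ran from 0.248 to 345 within the wild type, while the low set of ATMG01380 reached 25, and 0 of the 18 were called in any comparison. Reads shared with an overlapping gene stay open, since 5 of 15 such loci with a position overlapped another gene (33.3% against 30.5% of other loci, odds ratio 1.14, Fisher's exact p = 0.784). Reads split between neighbouring loci stay open too, since the median correlation of 0.05 lay on the side set beforehand as arguing against it but came from only 4 pairs. A biological explanation was not tested.

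Many more genes were called in ntrc-2cpab than in 2cpab, 645 against 22. At an unadjusted limma p under 0.05 the counts were closer, 3993 against 2838, where chance alone would give 819. The gap in calls may reflect responses of one size that straddle a threshold, or a larger response in ntrc-2cpab. With genes chosen without 1 ntrc-2cpab sample, that sample was compared with the 2cpab mean in the direction of the change, and the medians beyond 2cpab were 0.203 (53 genes), 0.0866 (197 genes) and 0.0319 (171 genes) for replicates 1, 2 and 3. All lay above 0 but the lowest was too small to decide. The genes were chosen by their change in ntrc-2cpab, which favours genes that changed more there. The reverse choice, by the change in 2cpab, was not made. Both explanations stay open.

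Other splits of the 6 samples of each comparison were tested as well, and with 10 splits a share under 0.05 cannot be reached. For 2cpab against wild type the real split gave 22 genes and the highest other 2, and for ntrc-2cpab against wild type 645 and 5, so that 1 split, the real one, reached the real count in each. Between the mutants 2 splits gave at least as many genes as the real count of 1, and the highest other gave 12.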
